A study of Homo sapiens with 12 samples.

How the data were processed

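Poly(A) RNA of H9 cells, wild type and SOX21-/-, was sequenced at days 0, 4 and 8 of neural differentiation, in 12 libraries. The deposited values were TPM, each gene's share of the transcripts scaled to a fixed total, per gene, made by the authors with Salmon 0.8.2 after base calling with CASAVA 1.7, with hg38 as the genome build, per the submitters' processing notes. The annotation release and the use of strand were not given in the sources used here, so antisense and overlapping genes are treated as uncertain. The library protocol in the labels names 3 sequencers, with reads of 50, 100 or 150 bases, and does not assign them to libraries. The table held 58219 gene identifiers and 0 columns of other series. Because TPM adds up to a fixed total, the number of reads behind each value, and with it the depth and its precision, is unknown. Reads were not reanalysed.

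The 12 libraries were grouped by genotype and day into 6 groups of 2, from their labels: WT1 and WT2 for wild type, S13 and S23 for SOX21-/-. Genes with a TPM of at least 1 in at least 2 libraries (24248) were tested on log2(TPM + 1), a pseudocount of 1, with limma 3.58.1 in R 4.3.3. A single model with a mean per group was fitted to all 12 libraries, with 6 residual degrees of freedom and 2.29 prior degrees of freedom, moderated variances with a trend on mean expression, two-sided tests and Benjamini-Hochberg adjustment within each comparison at 0.05. The comparisons were SOX21-/- against wild type at each day, the day steps within each genotype, and the 3 interaction contrasts between days. A gene was said to be listed at 0 where the table gave exactly 0, since such a value can be a failed estimate. Every adjusted p of a gene is from limma.

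A total of 32 gene lists covered regions of the developing nervous system, other germ layers, signalling pathways, gene families and cell states. Those with at least 5 tested members, 30 in number, were tested at each day with limma's camera at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over 90 tests. Members were counted by their adjusted p over all genes tested and adjusted over the list alone. The design, the lists, the rule for named genes and the alternatives were chosen before the data were examined, except where stated. By that rule SOX21, as the knocked-out gene, and WNT8B, which the title of the study names, were always named. The choice of WNT8B may thus not be independent of the submitters' own results, and it was also a member of the caudal forebrain and WNT ligand lists. At each day the 10 largest changes each way were named among genes that passed, had a mean TPM of at least 5 in the higher group and had both SOX21-/- libraries on the same side of both wild-type libraries, and for day steps and interactions the 5 largest each way. List members that passed could also be named. Some genes that met this rule are not reported here. Genes without a symbol, clone-type names, pseudogenes, and sex-linked marker genes were left out of the largest changes. POU5F1 at day 0, SOX21-AS1, DIO3 and BEGAIN as neighbours of DLK1, and genes shared between days were described after their values were seen.

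The alternatives were a pseudocount of 0.1, a filter at a TPM of 5 or no filter, median-of-ratios scaling, quantile normalization, moderation without the trend or with robust variances, only the libraries of 1 day, the line label as a random effect, the replicate number as a block, a threshold of 2-fold, an estimated correlation for the lists, rotation tests (fry), and each library left out in turn. Fits on nuclear protein-coding genes only, on days 4 and 8 only and on both together were added after seeing the data. Locations and gene types came from GENCODE v29 on GRCh38, matched to 57881 of the 58219 identifiers without version and to 55050 with version.

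The model was tested on simulated data with 24248 genes, of which 200 were changed, 50 at each size. At log2 changes of 0.5, 1, 2 and 4 it recovered 4%, 34%, 62% and 90% at day 0, 4%, 26%, 74% and 98% at day 4, and 2%, 26%, 72% and 94% at day 8. For the wild-type step from day 0 to day 4 it recovered 2%, 38%, 74% and 92%, and from day 4 to day 8 4%, 38%, 60% and 86%; for the SOX21-/- steps 4%, 30%, 62% and 78%, and 6%, 34%, 70% and 88%. For the interactions it recovered 0%, 4%, 50% and 66% from day 0 to day 4, 0%, 18%, 44% and 76% from day 4 to day 8, and 0%, 6%, 42% and 90% from day 0 to day 8. False calls numbered 2 to 8 per comparison. Each simulated gene had the same spread in all 6 groups and no floor at a TPM of 0. The simulation thus cannot show how many false calls arise where values near 0 at some days lower the shared spread. In the simulated list test, of 90 tests over 24248 genes, that of the raised list was called and 0 others were. The simulated genes were drawn independently, so it cannot show how many lists would be called through correlation between genes. In the data the estimated correlation ran from 0.00651 (pluripotency) to 0.658 (cholesterol synthesis).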

Results

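Poly(A) RNA was sequenced from H9 cells, an established human embryonic stem cell line, of wild-type and SOX21-/- genotype, at days 0, 4 and 8 of neural differentiation. SOX21 encodes a transcription factor of the SOX family that is made in neural progenitors. The 12 libraries fell into 6 groups of 2: WT1 and WT2 for wild type, and S13 and S23 for the SOX21-/- label, at each day. Whether the 2 libraries of a group come from separate clones, and whether a label repeated across days marks the same culture, is not given in the sources used here, so what n = 2 and the p-values stand for is unknown. Values were in TPM, a measure of each gene's share of the transcripts in a library, and add up to the same total in every library. They keep no record of read numbers, so the depth of each library is unknown. Of 58219 genes, 24248 reached 1 TPM in at least 2 libraries and were tested. Across genes, which are not independent replicates, Pearson correlations between the 2 libraries of a group ran from 0.954 to 0.962. Fold changes are on the log2(TPM + 1) scale, which understates the change of genes with low values, and the p-values measure only the spread between these libraries.

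Day 0 libraries stood apart from the rest in the makeup of gene types. Nuclear protein-coding genes held 55.9% to 56.4% of the TPM at day 0 and 83.5% to 87.1% at days 4 and 8. Mitochondrial tRNA genes held 6.57% to 8.40% at day 0 and 0.0588% to 0.0713% later. Processed pseudogenes held 11.1% to 12.4% at day 0 and 0.454% to 0.677% later, and miRNA genes held 3.45% to 3.75% at day 0 and 0.239% to 0.364% later. Between 15347 and 15490 genes reached 1 TPM at day 0, against 17586 to 19834 at days 4 and 8.

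**Figure D1:**
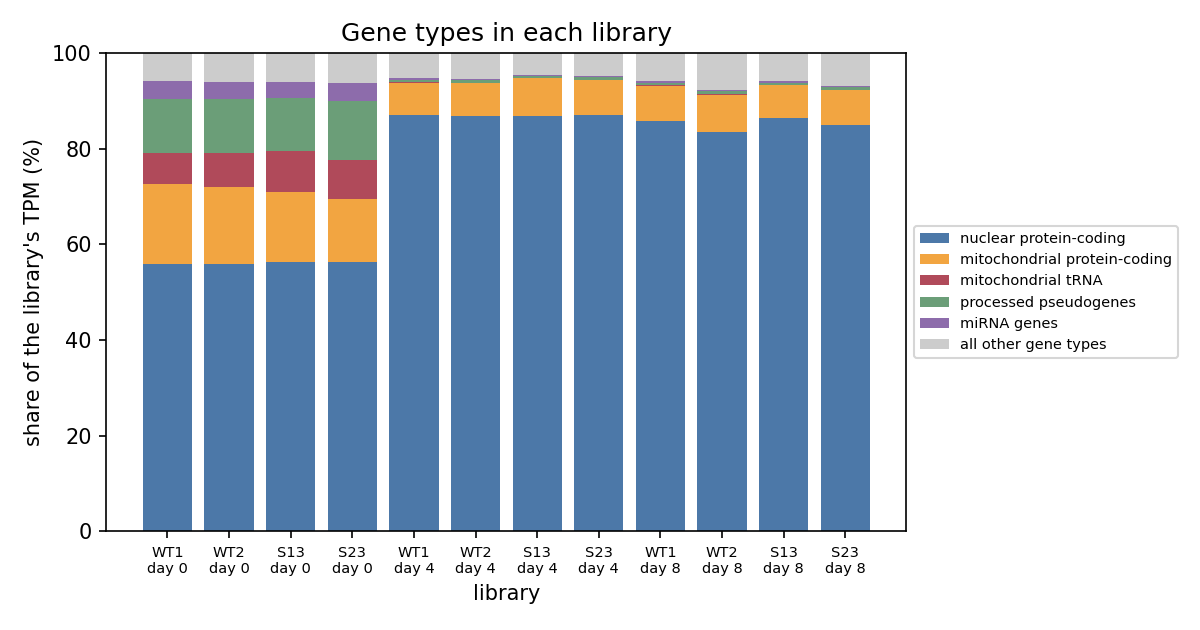
Share of each library's TPM (%) by gene type, 1 bar per library, for WT1, WT2, S13 and S23 at days 0, 4 and 8. Nuclear protein-coding genes held 55.9% to 56.4% in the 4 day 0 libraries and 83.5% to 87.1% in the other 8.

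For SOX21, the targeted gene, no difference between the genotypes was called at any day. It has a single exon (chromosome 13, 94709622 to 94712399, minus strand, GRCh38). At day 0 it was at 1.26 and 1.39 TPM in WT1 and WT2 and at 1.62 and 1.84 TPM in S13 and S23. At day 4 it was at 156 and 166 TPM in wild type and at 162 and 143 TPM in S13 and S23, and at day 8 at 129 and 100.04 TPM and 253 and 69.9 TPM. The log2 fold changes were 0.23, -0.085 and 0.23 (SE 0.47, n = 2 per group, limma adjusted p = 1, 1 and 0.898). Without S23 at day 8 the last became 1.15 (adjusted p = 0.0352). The level of SOX21 mRNA did not bear out the genotype label, and a mutation that leaves the mRNA in place would not be seen in gene-level TPM. All directions below are between the libraries labelled SOX21-/- and those labelled wild type. SOX21-AS1, the neighbouring antisense gene (chromosome 13, 94712716 to 94716246, plus strand), was higher at day 8 in the libraries labelled SOX21-/-, at 165 and 108 TPM against 57.2 and 52.1 TPM (log2 fold change 1.28, SE 0.18, adjusted p = 0.00987). It was chosen after its values were seen.

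**Figure D2:**
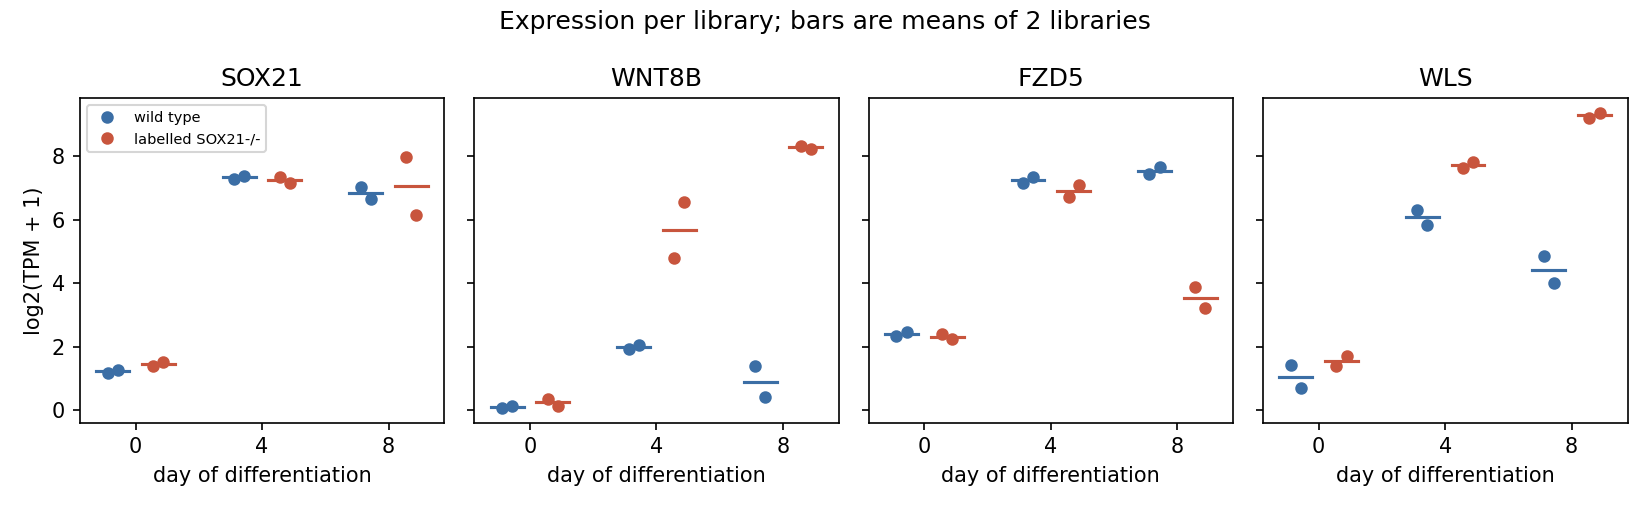
Expression of SOX21, WNT8B, FZD5 and WLS as log2(TPM + 1) by day of differentiation, 1 point per library, with lines at the means of 2 libraries; blue is wild type and red is the SOX21-/- label. WNT8B and WLS at day 8 were above wild type in both labelled libraries, FZD5 was below, and SOX21 overlapped.

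The comparison at day 8 asked how regional genes of the neural progenitors differed between the genotypes. WNT8B, which encodes a secreted WNT ligand (chromosome 10, 100463041 to 100483744, plus strand), was at 322 and 303 TPM in S13 and S23 against 1.60 and 0.317 TPM in WT1 and WT2 (log2 fold change 7.40, SE 0.52, adjusted p = 0.000410). WLS, which carries WNT proteins to the cell surface, rose to 628 ± 52.8 TPM (SD, n = 2) from 21.5 ± 9.02 TPM (log2 fold change 4.87, SE 0.32, adjusted p = 0.000321). The genes for the WNT receptors FZD5 and FZD8 fell, with log2 fold changes of -4.01 and -3.21 (adjusted p = 0.000204 and 0.000492). Of the genes tested, limma called 676, of which 357 were higher and 319 lower in the libraries labelled SOX21-/-. Of the 676, 473 were protein-coding and 455 differed by at least 2-fold.

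Beside WNT8B and WLS, large increases at day 8 were in HES3, a repressor of neural differentiation (4.76), GCNT1, a glycosyltransferase (4.05), the growth factor receptor FGFR2 (3.72), TMEM132C (3.55), the dopamine receptor DRD4 (3.00) and the homeobox genes OTX1 (2.97) and BARHL1 (2.96). Beside both frizzled genes, large decreases were in PKDCC, a secreted kinase (-4.75), DLK1, an imprinted NOTCH-like ligand (-3.95), MGST1 (-3.87), the deiodinase DIO3 (-3.79), BEGAIN (-3.60) and the axon guidance gene SEMA5A (-3.18). In wild type HES3 fell from day 4 to day 8 (-5.29), while its genotype effect rose by 4.24, which is less than that fall. The fitted mean of HES3 thus also fell in the libraries labelled SOX21-/-, by less, and its day 8 difference was not a rise from day 4. At day 8 HES3 was at 44.4 and 73.6 TPM against 1.22 and 1.09 TPM in wild type. PKDCC was at 8.64 and 5.08 TPM against 186 and 226 TPM, and OTX1 at 91.7 and 103 TPM against 13.3 and 10.03 TPM. Adjusted p for these genes ran from 3.44e-05 for MGST1 to 0.0131 for DRD4. MIR8086 (adjusted p = 0.0220), listed at 0 in S13 and S23 and at 15.8 and 6.09 TPM in WT1 and WT2, is a short precursor whose reads can be shared with the gene around it, so its value is uncertain. Its call was lost without any 1 day 8 library (0.0509 to 0.117), that of DRD4 without WT2, S13 or S23 at day 8 (0.0631 to 0.102) and that of GCNT1 without S23 at day 8 (0.0510).

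At day 8 the medians of the caudal and rostral forebrain lists had opposite signs, though members of the rostral list went both ways. Of 17 tested genes of the caudal forebrain, 5 were higher and none was lower in the libraries labelled SOX21-/- (12 and 1 when adjusted over the list alone), with a median log2 fold change of 0.91 and a camera adjusted p = 6.23e-07 (adjusted p = 0.264 with an estimated correlation). They were WNT8B, the homeobox genes LHX5 (2.46), BARHL1 and EMX2 (2.44), and the nuclear receptor NR2F2 (1.75). Of 17 genes of the rostral forebrain and eye field, 4 were lower and 2 higher (11 and 4 when adjusted over the list alone), with a median of -0.76 and a camera adjusted p = 0.00208 (adjusted p = 0.462 with an estimated correlation). Among its members SIX3 (-2.29), VAX2 (-2.05) and VAX1 (-1.83) fell, while FEZF2 (1.79), which is made in the developing forebrain, rose. SIX3 was at 12.2 and 7.79 TPM against 46.0 and 58.2 TPM, LHX5 at 122 and 174 TPM against 27.7 and 23.8 TPM, and NR2F2 at 85.9 and 102 TPM against 29.6 and 24.8 TPM. The rostral list was not called without WT1 at day 8 (adjusted p = 0.0754). VAX1 was not called without S23 at day 8 (adjusted p = 0.069) and BARHL1 not without WT2 at day 8 (adjusted p = 0.0795). EMX2 and FEZF2 lost their calls without any 1 of the 4 day 8 libraries, and without some libraries of other days (10 leave-outs each; adjusted p = 0.0693 to 0.205 and 0.0709 to 0.229).

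**Figure D3:**
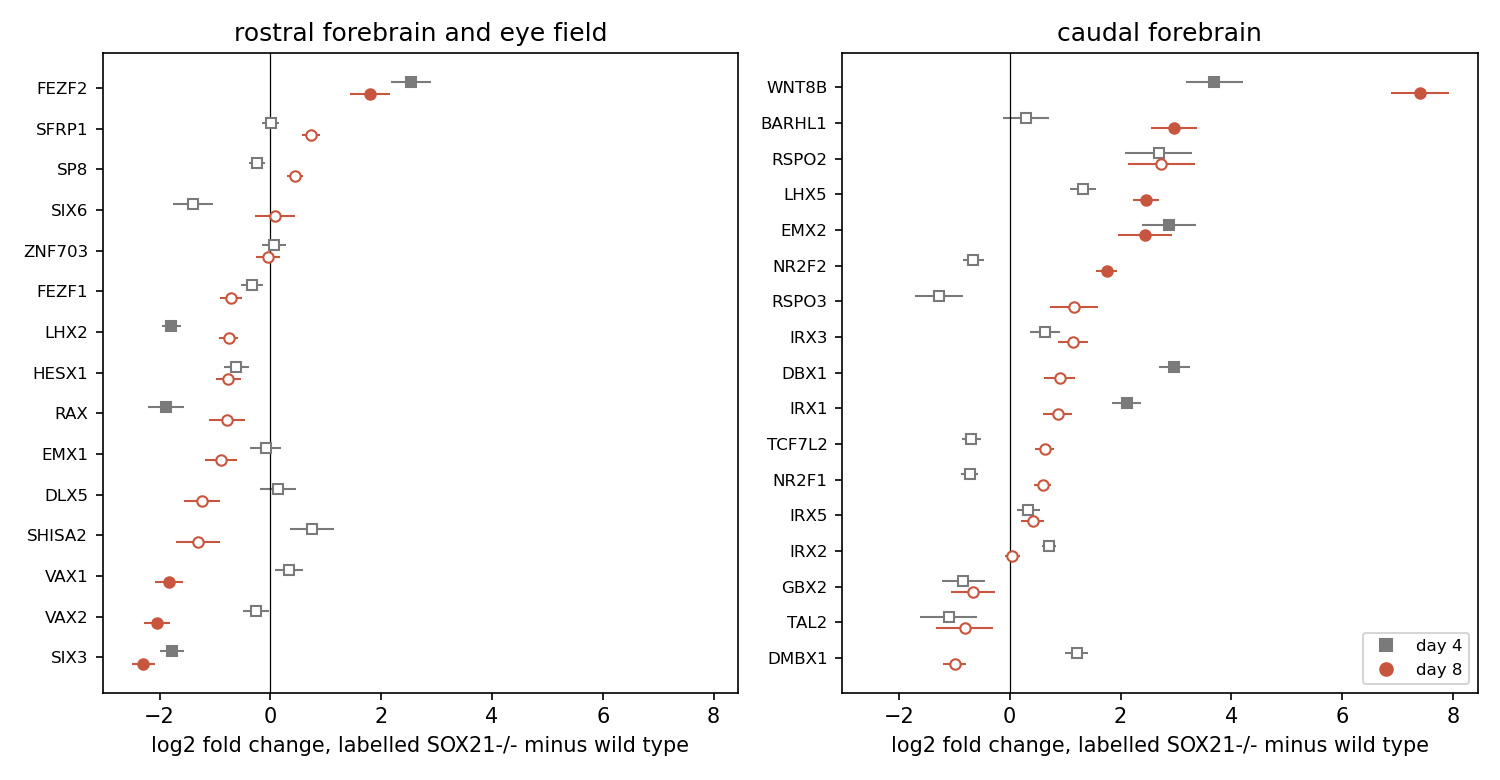
Log2 fold change with its SE, libraries labelled SOX21-/- minus wild type, for 15 genes of the rostral and 17 of the caudal forebrain list; squares are day 4, circles day 8, and filled symbols have an adjusted p under 0.05. At day 8, WNT8B was at 7.40 and SIX3 at -2.29.

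Other gene groups also differed at day 8, most of them higher in the libraries labelled SOX21-/-. Among 24 early neural progenitor genes, OTX1, DACH1 (1.16), MSI1 (1.07) and POU3F2 (0.88) rose and ZIC1 (-3.15) fell, with 9 higher and 1 lower when adjusted over the list alone (median 0.40, camera adjusted p = 9.83e-05; adjusted p = 0.581 with an estimated correlation). Among 16 NOTCH pathway genes, HES4 (1.17), JAG1 (0.88) and NRARP (0.70) rose and none fell, with 9 higher when adjusted over the list alone (median 0.62, camera adjusted p = 8.88e-05; adjusted p = 0.462 with an estimated correlation). Of 11 dorsal midline genes, BAMBI (1.21) and WNT2B (1.13) rose and ZIC4 (-1.59) and ZIC1 fell, with 6 higher and 2 lower when adjusted over the list alone (median 0.80, camera adjusted p = 0.0206; adjusted p = 0.581 with an estimated correlation). Of 15 canonical WNT target genes, BAMBI, CCND1 (0.77) and TNFRSF19 (1.17) rose, with 4 higher when adjusted over the list alone (median 0.24, camera adjusted p = 0.0370; adjusted p = 0.756 with an estimated correlation). Of 19 cadherin and adhesion genes only PCDH18 (1.02) passed, and 2 when adjusted over the list alone (median 0.39, camera adjusted p = 0.0341; adjusted p = 0.581 with an estimated correlation). Of 22 cell cycle genes, PCNA (-0.68), MCM3 (-0.44) and MCM2 (-0.61) fell, with 7 lower when adjusted over the list alone (median -0.16, camera adjusted p = 0.0148; adjusted p = 0.769 with an estimated correlation). None of 13 mitochondrially encoded genes passed, and 2 were lower when adjusted over the list alone (median -0.13, camera adjusted p = 0.0370; adjusted p = 0.791 with an estimated correlation). Many of these members lost their calls when 1 library was left out. NRARP did so without any 1 of the 12 libraries (0.0576 to 0.248), WNT2B and TNFRSF19 in 10 leave-outs (0.05005 to 0.171 and 0.0746 to 0.243), ZIC1 and PCNA in 9 (0.0662 to 0.212 and 0.0509 to 0.181), JAG1 in 8 (0.0651 to 0.221) and MCM2 and MCM3 in 6 (0.0546 to 0.199 and 0.0581 to 0.181). BAMBI and POU3F2 lost theirs without any 1 day 8 library (0.0524 to 0.0978 and 0.0517 to 0.175), HES4 and PCDH18 without WT2, S13 or S23 at day 8 (0.0847 to 0.158 and 0.0665 to 0.0839) and CCND1 without WT1, WT2 or S13 (0.0857 to 0.155). MSI1 and ZIC4 lost theirs without WT2 or S23 (0.0784 to 0.0865 and 0.140 to 0.151) and DACH1 without WT2 (0.0677). The dorsal midline list was not called without WT1 (adjusted p = 0.122) or S13 (0.185) at day 8, and the cell cycle list not without WT1 (0.0535) or S23 (0.347, median 0.0075). The canonical WNT list lost its call without S23 at day 0 (0.052), WT2 at day 4 (0.0516), or WT1 (0.0535), WT2 (0.0973) or S13 (0.389) at day 8. The cadherin list lost its call without S13 (0.0515) or S23 (0.0544) at day 0, or WT1 (0.0535), WT2 (0.0839) or S13 (0.0937) at day 8. The mitochondrial list lost its call without WT2 (0.317) or S13 (0.604) at day 8, with median-of-ratios scaling (0.0603) and with quantile normalization (0.0903).

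Many of these day 8 calls ended when 1 library was left out. Leaving out any 1 library also lowers the residual degrees of freedom, so a lost call does not show reliance on that library. All 68 called genes followed at day 8 kept their direction in every alternative they entered. Leaving out 1 library could not reverse the largest changes, since the naming rule put both SOX21-/- libraries on the same side of wild type. Alternatives that changed only the spread or the filter leave a fold change as it is, so the kept directions were largely fixed in advance. The count of called genes was 316 without WT1 at day 8, 170 without WT2, 332 without S13 and 229 without S23. It was 34 with only the 4 day 8 libraries in the fit and 312 with only days 4 and 8. Of the 676 called genes, 269, WNT8B among them, were under 1 TPM in all day 0 libraries. In 58 all 8 libraries of the other days were listed at 0. Such low values can lower the spread that the shared fit assigns to a gene, and with it the SE and adjusted p. Lower genes outnumbered higher ones without S13 at day 8 (143 higher and 189 lower) and with quantile normalization (381 and 390). Of 68 called genes followed at day 8, the calls ended for 25 without WT1 (adjusted p = 0.0511 to 0.1503), 36 without WT2 (0.05003 to 0.248), 25 without S13 (0.05005 to 0.177) and 33 without S23 (0.051 to 0.225) at that day. A pseudocount of 0.1 ended 17 of the 68 calls (0.0510 to 0.183). The fit of days 4 and 8 alone ended 24 (0.0571 to 0.156). Having no filter ended 11 (0.0520 to 0.0702), and median-of-ratios scaling and moderation without the trend 10 each (0.0515 to 0.0783 and 0.0509 to 0.103). Calls that held under every alternative were those for WNT8B, WLS, HES3, TMEM132C, OTX1, PKDCC, FZD5, MGST1, DIO3, BEGAIN, FZD8, SEMA5A, SOX13, EPHA7 and PLAGL1. Those for SIX3, VAX2, LHX5, NR2F2, FGFR2 and DLK1 ended only when the fit held the day 8 libraries alone (adjusted p = 0.0764, 0.114, 0.0565, 0.0565, 0.0711 and 0.0961).

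At day 4 the same question was asked of cells midway through differentiation. WNT8B was at 26.7 and 94.3 TPM in S13 and S23 against 2.78 and 3.19 TPM in WT1 and WT2 (log2 fold change 3.69, SE 0.52, adjusted p = 0.0289). Of the caudal forebrain list, the homeobox genes DBX1 (2.97), IRX1 (2.11) and EMX2 (2.87) were also higher in the libraries labelled SOX21-/-. The eye field and forebrain genes RAX, LHX2 and SIX3 fell by 1.89, 1.78 and 1.77 on the log2 scale. Limma called 188 genes, 58 higher and 130 lower, of which 119 were protein-coding and 123 differed by at least 2-fold. That split turned with the scaling of the values, to 61 higher and 36 lower with median-of-ratios scaling and to 72 higher and 56 lower with quantile normalization. Both of these bring the median change of all genes tested, -0.12 as deposited, to 0. With nuclear protein-coding genes only it was 63 higher and 192 lower, and 78 and 328 when these were fitted on days 4 and 8 only, both chosen after seeing the data. At day 4, 17586 and 17949 genes reached 1 TPM in S13 and S23 against 18870 and 18884 in WT1 and WT2, and 26909 and 26876 against 28119 and 27696 were above 0.

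The other large increases at day 4 were in the phosphatase inhibitor PPP1R17 (3.12), TMEM132C (3.06), the forkhead gene FOXB1 (3.02), ENPP2, which makes lysophosphatidic acid (2.84), FEZF2 (2.54) and OTX1 (2.27). The other large decreases were in the protocadherin PCDHB5, ANKS1B (-2.36), the neurotrophin receptor NGFR (-1.39), FNDC5 (-1.35) and MIR1915 (-1.33). DBX1 was at 111 and 173 TPM against 18.2 and 15.5 TPM, LHX2 at 18.2 and 20.5 TPM against 60.2 and 78.9 TPM, and TMEM132C at 9.29 and 15.6 TPM against 0.547 and 0.582 TPM. Adjusted p for the 20 genes with the largest changes ran from 0.00487 for TMEM132C to 0.0494 for FNDC5. These 20 include MIR548AO, listed at 0 in wild type and at 10.1 and 10.7 TPM in S13 and S23, and MIR4701 and MIR548E, at 25.8 and 9.62 TPM and 2.58 and 7.44 TPM in wild type and listed at 0 in S13 and S23. Such miRNA precursors are uncertain, since reads of the genes around them can be counted for them. PCDHB5 was lower at each day, with log2 fold changes of -1.53, -2.67 and -2.19 at days 0, 4 and 8 (adjusted p = 0.0419, 0.00605 and 0.00292). Reads can be shared among the clustered protocadherins, and its day 0 call was lost without any 1 of the 12 libraries (0.0574 to 0.153).

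Gene groups at day 4 differed in direction. Of 17 caudal forebrain genes, 4 were higher and none lower in the libraries labelled SOX21-/- (8 and 4 when adjusted over the list alone; median 0.63, camera adjusted p = 3.74e-05; adjusted p = 0.308 with an estimated correlation). The rostral list was not called (camera adjusted p = 0.673), with FEZF2 higher, LHX2, SIX3 and RAX lower, and 2 higher and 4 lower when adjusted over the list alone. Of 15 canonical WNT targets, TNFRSF19 (1.91) rose, with 6 higher and 1 lower when adjusted over the list alone (median 0.33, camera adjusted p = 0.000157; adjusted p = 0.491 with an estimated correlation). Of 18 cholesterol synthesis genes, MVD (-0.80) fell, with 13 lower when adjusted over the list alone (median -0.68, camera adjusted p = 3.3e-05; adjusted p = 0.756 with an estimated correlation). Of 21 imprinted genes, MEST (-0.70) fell, with 1 higher and 6 lower when adjusted over the list alone (median -0.28, camera adjusted p = 0.0272; adjusted p = 0.581 with an estimated correlation). Of 22 clustered protocadherins, PCDHB5 alone passed, over all genes and when adjusted over the list alone, and none was above 0 (median -0.39, camera adjusted p = 0.0102; adjusted p = 0.581 with an estimated correlation). No mitochondrially encoded gene passed, and 3 of 13 were higher when adjusted over the list alone (median 0.12, camera adjusted p = 0.00208; adjusted p = 0.756 with an estimated correlation); with quantile normalization the median was -0.083 (adjusted p = 0.142). The median, the mean and the test of the early neural list differed in sign at day 4, at -0.10, 0.15 and upward (camera adjusted p = 0.346). In that list, among others, OTX1 and POU3F2 (1.02) were higher and ZBTB16 (-0.92) was lower, with 4 higher and 3 lower when adjusted over the list alone. MVD lost its call without any 1 of the 12 libraries (0.0547 to 0.166), ZBTB16 in 11 leave-outs (0.0679 to 0.264), OTX1 and POU3F2 in 10 (0.0508 to 0.184 and 0.0571 to 0.187), MEST in 8 (0.0577 to 0.170) and TNFRSF19 without WT1 or WT2 at day 4 (0.117 to 0.13). The imprinted list was not called without WT2 (0.134) or S23 (0.107) at day 4, WT1 at day 0 (0.0546), or WT1 (0.0535) or WT2 (0.0514) at day 8, or in the fit of days 4 and 8 (0.0769). The protocadherin list was not called without WT2 (0.0816) or S23 (0.0845) at day 4 or with quantile normalization (0.086), and the mitochondrial list not without S13 at day 4 (median -0.035, adjusted p = 0.0592).

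Many day 4 calls ended when 1 library was left out, including libraries of other days. Leaving out any 1 library also lowers the residual degrees of freedom, so a lost call does not show reliance on that library. All 35 called genes followed at day 4 kept their direction in every alternative they entered. For the largest changes the naming rule fixed this in advance when 1 library was left out. Without WT1 at day 4 the count was 14, without WT2 19 and without S13 86, it was 73 or 74 without any 1 day 0 library, and 114 without WT1 or WT2 at day 8. With only the 4 day 4 libraries or only days 4 and 8 limma called 0 genes (3288 and 3874 with an unadjusted p under 0.05). Of the 188 called genes, 84, WNT8B among them, were under 1 TPM in all day 0 libraries. In 19 all 8 libraries of the other days were listed at 0. Such low values can lower the spread that the shared fit assigns to a gene. All 35 called genes followed at day 4 lost their calls in the fit of days 4 and 8 (adjusted p = 0.0602 to 0.108). With only nuclear protein-coding genes 406 genes were called on days 4 and 8. Both fits of these 2 days were chosen after seeing the data. WNT8B lost its day 4 call without WT1 (adjusted p = 0.128) or WT2 (0.151) at day 4, and without WT1 (0.0577), WT2 (0.0574), S13 (0.0605) or S23 (0.0599) at day 0. A pseudocount of 0.1 ended 19 of the 35 calls (0.0579 to 0.187), among them those of WNT8B (0.0681), SIX3 (0.0696), PPP1R17 (0.0792) and RAX (0.126). Median-of-ratios scaling ended 15 (0.0509 to 0.127), no filter 14 (0.0504 to 0.0756), moderation without the trend 14 (0.0516 to 0.0994), robust variances 10 (0.0504 to 0.0522) and quantile normalization 8 (0.0617 to 0.134). Leaving out 1 library ended 31 of the 35 calls for WT1 at day 4 (0.0572 to 0.179), 32 for WT2 (0.0604 to 0.264), 18 for S13 (0.0571 to 0.169) and 20 for S23 (0.051 to 0.101), and 15 to 25 for each library of the other days.

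Before differentiation, the comparison at day 0 asked whether the genotypes already differed as stem cells. POU5F1, a core pluripotency factor, was at 1743 and 1744 TPM in wild type and at 1507 and 1679 TPM in the libraries labelled SOX21-/- (log2 fold change -0.13, SE 0.31, adjusted p = 1). WNT8B was at 0.0486 and 0.0983 TPM and at 0.269 and 0.0971 TPM (adjusted p = 1). Limma called 93 genes, 39 higher and 54 lower, of which 12 were protein-coding, and in 61 of the 93 both libraries of 1 genotype were listed at 0. The higher protein-coding genes were SCNN1D, a sodium channel subunit (3.07), SAMD12 (1.49), MYLK, which phosphorylates myosin light chains (0.80), and MAGED1 (0.52).

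Of the day 0 calls 81 were not protein-coding, and among the largest were small RNA genes, which poly(A) libraries sample poorly and whose reads can come from the genes around them, so their values are uncertain. MIR663B was at 102 and 102 TPM in S13 and S23 and listed at 0 in WT1 and WT2. SNORD116-14 was at 32.8 and 20.9 TPM and MIR572 at 59.3 and 10.3 TPM in S13 and S23, and both were listed at 0 in wild type. SNORA5B was at 8.28 and 16.2 TPM and listed at 0 in wild type, and MIR1302-3 at 10.7 and 15.97 TPM against 1.48 and 0. SNORD6, MIR8086, SNORD87, SNORA10, MIR5587, SNORD99, SNORD1C, SNORD116-22, MIR6514 and SNORA2A were the most reduced. SNORD87 was at 33.4 and 10.4 TPM in wild type and listed at 0 in S13 and S23, and SNORA10 at 113 and 135 TPM and 2.71 and 9.73. In 62 of the 93 genes all 8 libraries of days 4 and 8 were listed at 0, which lowers the spread that the shared fit assigns to the gene. With only the 4 day 0 libraries 45 genes were called, and with nuclear protein-coding genes alone 8. Without a filter on low values the count was 159 and with median-of-ratios scaling 154. It was 59 without S13 or S23 at day 8. The split depended on single day 0 libraries: it turned to 67 higher and 31 lower without WT1 and 83 and 31 without WT2, and was 18 and 80 without S13 and 19 and 87 without S23. Of these calls 31, 35, 35 and 29 were among the 93. Of 20 called genes followed at day 0, only SNORD116-14 and MIR6514 kept their calls under every alternative they entered, which leaves out the fit on protein-coding genes. All 20 kept their direction, which the naming rule fixed in advance for the largest changes when 1 library was left out. Among the small RNA genes, the calls for MIR663B, MIR572, MIR1302-3, SNORD6, MIR8086 and SNORD99 ended when certain single libraries were left out. The calls for SCNN1D, SAMD12, MYLK and MAGED1 were lost in 4, 10, 9 and 10 leave-outs (adjusted p = 0.0567 to 0.0685, 0.0507 to 0.109, 0.0563 to 0.123 and 0.0563 to 0.137).

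In all, 3 gene lists were called at day 0 although none of their members passed, apart from 1 axon guidance gene when adjusted over the list alone. Of 19 hypoxia and glycolysis genes, 18 were above 0 in the libraries labelled SOX21-/- (median 0.37, camera adjusted p = 8.88e-05; adjusted p = 0.756 with an estimated correlation). The medians of 29 axon guidance genes and 13 mitochondrially encoded genes were 0.13 and -0.11 (camera adjusted p = 0.0226 and 0.0272; adjusted p = 0.581 and 0.791 with an estimated correlation). The hypoxia list was not called without WT1 (median -0.032, adjusted p = 0.954) or S23 (0.0544) at day 0, and the axon guidance list not without WT1 (0.0942), S13 (0.0721) or S23 (0.148). The mitochondrial list was not called without WT1 (0.306) or S23 (0.545).

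Apart from these lists, several gene families held single members that passed at day 8. FZD5 and FZD8 fell among 22 WNT receptor and antagonist genes, of which 1 was higher and 3 lower (4 and 3 when adjusted over the list alone). SOX13 (1.79) rose among 14 SOX family genes, of which 2 were higher (3 and 1 lower when adjusted over the list alone). The other, SOX14, was at 3.4 and 5.06 TPM and listed at 0 in wild type. Of 29 axon guidance genes, 3 were higher and 1 lower (4 and 1 when adjusted over the list alone), among them the ephrin receptor gene EPHA7 (2.63) and the ephrin gene EFNB2 (1.35). Of 21 imprinted genes, 2 were higher and 3 lower (4 and 6 when adjusted over the list alone), with DLK1 and RTL1 (-1.63) lower and the growth suppressor gene PLAGL1 (2.03) higher. Of 12 neuron genes, NEUROD4 (2.37), a factor that drives neuron formation, rose and DCX (-2.49), a microtubule protein of young neurons, fell (5 and 3 when adjusted over the list alone). Neither was called without WT2 at day 8 (adjusted p = 0.0514 and 0.0565).

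Among 30 lists tested at the 3 days, 16 were called at none of them. Their camera adjusted p over the 3 days ran 0.139 to 0.763 for pluripotency, 0.337 to 0.945 for neurons, 0.229 to 0.945 for the SOX family, 0.141 to 0.872 for WNT ligands, 0.679 to 0.980 for WNT receptors and antagonists and 0.228 to 0.977 for midbrain and isthmus. For the ventral neural tube it ran 0.125 to 0.673, for neural crest and placode 0.311 to 0.938, for mesoderm 0.129 to 0.736, for epithelium and surface ectoderm 0.13 to 0.977 and for the p53 response 0.0617 to 0.344. For the FGF and ERK response it ran 0.228 to 0.477, for the BMP and TGF-beta response 0.5 to 0.945, for amino acid and unfolded protein stress 0.141 to 0.858, for replication-dependent histones 0.139 to 0.945 and for genes of 20q11.21 0.763 to 0.834. The median, the mean and the test differed in sign for the uncalled lists of WNT ligands at days 0 and 4, WNT receptors at days 0 and 8, pluripotency at day 8, dorsal midline, ventral neural tube, hypoxia, stress and axon guidance at day 4. They also differed for neural crest at day 8, the BMP response and protocadherins at day 0, and 20q11.21 at each day. The hindbrain and spinal cord list had 1 tested member and the endoderm list 3, so neither was tested as a list. CXCR4, a chemokine receptor gene in the endoderm list, rose at day 4 (1.56) and day 8 (1.74) and was the only member called over all genes or when adjusted over the list alone. CXCR4 lost its day 8 call without WT1, WT2 or S23 at day 8 (adjusted p = 0.0515 to 0.0795) and its day 4 call in 11 leave-outs (0.0531 to 0.152).

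Days 4 and 8 shared part of their calls. In the libraries labelled SOX21-/-, 21 genes were higher at both days (0.854 expected of independent lists of those sizes), among them WNT8B, OTX1, TMEM132C, FEZF2 and EMX2, and 17 were lower at both (1.71 expected), among them SIX3 and PCDHB5. Another 13 were called in opposite directions (2.68 expected). Calls at both days use the same spread for each gene, so lists of this kind are not independent and these expected numbers are no test of overlap. Of the 58 genes higher at day 4, 43 had the same sign at day 8, as had 68 of the 130 lower ones.

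How the genotype effect changed between days was tested by interaction contrasts. From day 4 to day 8 the effect changed for 270 genes, 180 of them protein-coding, with the effect at day 8 above that at day 4 for 191 and below it for 79. It rose for HES3 (4.24), FGFR2 (3.49) and WLS (3.20) and fell for PKDCC (-4.99), DIO3 (-3.89), FZD5 (-3.65) and ADCYAP1R1, a neuropeptide receptor gene (-3.58), with adjusted p from 0.00117 for PKDCC to 0.0238 for WLS. For WNT8B the change was 3.71 (SE 0.73, adjusted p = 0.0584) from day 4 to day 8 and 7.27 (SE 0.73, adjusted p = 0.00380) from day 0 to day 8. The former was called with a filter at 5 TPM (3.71, adjusted p = 0.0499), without S23 at day 4 (4.60, 0.0167), and with protein-coding genes only, on all days (3.79, 0.0250) or days 4 and 8 (0.0391). From day 0 to day 8 the effect changed for 228 genes (130 upward, 98 downward), and from day 0 to day 4 for 99 (41 upward, 58 downward), of which 32 were protein-coding. The latter included DDIT4, a stress gene (-2.14), and SCNN1D (-3.90). The splits depended on scaling. From day 4 to day 8 the split narrowed to 58 upward and 46 downward with median-of-ratios scaling and 114 and 100 with quantile normalization. From day 0 to day 4 it turned to 68 and 53 or 58 and 51 under the same scalings. The median interaction of all genes was 0.12 and -0.15. From day 4 to day 8 the count was 54 (WT1 at day 4) to 135 (S13 at day 0) without any 1 library except S23 at day 4, and 242 without that one. Leaving out 1 library gave 89 (WT2 at day 8) to 209 (S13 at day 4) from day 0 to day 8 and 38 (WT1 at day 4) to 80 (S23 at day 0) from day 0 to day 4. The split from day 0 to day 4 also depended on single day 0 libraries: it was 6 upward and 45 downward without WT1 and 12 and 51 without WT2, and turned to 53 and 13 without S13 and 56 and 24 without S23. Without WT1 at day 4 it turned to 21 and 17 and without S13 at day 4 to 36 and 25. From day 0 to day 8 it turned to 41 and 64 without WT1 and 43 and 72 without WT2 at day 0. With the replicate number as a block, 17 genes were called from day 4 to day 8, 22 from day 0 to day 4 and 98 from day 0 to day 8. The block ended the calls of FGFR2 (adjusted p = 0.0581), ADCYAP1R1 (0.0878), DDIT4 and SCNN1D (0.0769 each). The day 4 to day 8 calls for HES3, PKDCC, DIO3 and FZD5 held under every alternative. In contrast, WLS, FGFR2 and ADCYAP1R1 each lost theirs without WT1, WT2 or S13 at day 4. They also lost them at day 8 without WT2, S13 or S23 (WLS), S23 (FGFR2), and WT2 or S23 (ADCYAP1R1) (adjusted p = 0.0619 to 0.0981, 0.0533 to 0.0708 and 0.0624 to 0.0840). With a pseudocount of 0.1 WLS was not called (0.0654), nor with days 4 and 8 only (0.0516). FGFR2 was also not called with days 4 and 8 only (0.0668), nor were WLS and ADCYAP1R1 with median-of-ratios scaling (0.0549 and 0.0541). DDIT4 and SCNN1D lost theirs in 10 leave-outs each (0.0632 to 0.131 and 0.0511 to 0.113).

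The day steps in wild type followed genes along neural differentiation. From day 0 to day 4 the median change was 3.03 for the early neural list and -1.79 for the pluripotency list, which were not tested as lists here. POU5F1 was at 1743 and 1744 TPM at day 0, 20.5 and 32.4 TPM at day 4 and 0.895 and 0.508 TPM at day 8. DLK1 (8.80), GREB1L (7.41), PRTG, a receptor of early neural tissue (7.19), the secreted protein gene SMOC1 (7.12) and the eye field gene RAX (6.61) rose most by day 4, and SOX21 rose by 6.13. By day 8 the NOTCH effector HES5 (6.47) and WNT7B (4.82) rose from day 4. The natriuretic peptide gene NPPB went from listed at 0 to 55.1 and 61.1 TPM, and HES3 (-5.29) and POU5F1 (-3.99) fell. Between days 0 and 4, 15931 genes differed, 13177 higher and 2754 lower at day 4, and between days 4 and 8, 3058 differed, 1848 higher and 1210 lower at day 8. With median-of-ratios scaling the splits were 5557 to 6587 and 1193 to 1434, and with quantile normalization 7632 to 4685 and 1407 to 1453. The median log2 fold change of all genes from day 0 to day 4 was 0.91. The largest decreases by day 4 were of short transcripts, which are uncertain. MIR6723, a copy of mitochondrial sequence, went from 28625 and 27712 TPM to listed at 0, MT-TL1 from 3817 and 4793 TPM and MIR3652 from 1120.5 and 1344 TPM to listed at 0. MT-TN went from 9624 and 11466 TPM to 6.45 and 0 TPM, and MT-TA from 9119 and 9199 TPM to 6.73 and 0 TPM. MIR302A, SNORD116-2 and MIR135A1 were listed at 0 at day 8, from 16.8 and 20.7, 52.5 and 11.4, and 15.0 and 19.2 TPM at day 4. The count from day 4 to day 8 was 1065 without WT1 and 1038 without WT2 at day 4, and 1043 without WT1 and 1342 without WT2 at day 8. SNORD116-2 and MIR135A1 lost their calls without any 1 of these 4 libraries (0.0540 to 0.156 and 0.0558 to 0.158).

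In the libraries labelled SOX21-/- the same steps took POU5F1 from 1507 and 1679 TPM at day 0 to 24.2 and 30.7 TPM at day 4 and 0.283 and 1.41 TPM at day 8. The median change from day 0 to day 4 was 3.29 for the early neural list and -1.48 for the pluripotency list. By day 4 DLK1 (7.52), GREB1L (7.15), DBX1 (7.10), PRTG (6.97) and ATP6V1G2-DDX39B (6.64) rose most. The last is a read-through transcript that shares sequence with both of its genes, so its value is uncertain. SOX21 rose by 5.81 and WNT8B by 5.44 by day 4, and WNT8B by another 2.61 by day 8 (adjusted p = 0.00835). HES5 (5.81), WNT7B (5.10) and C1orf61 (5.10) rose by day 8, while PKDCC (-5.50), POU5F1 (-4.01), the matrix gene FBLN1 (-3.93) and the homeobox gene PAX2 (-3.87) fell. Between days 0 and 4, 14688 genes differed, 11664 higher and 3024 lower at day 4, and between days 4 and 8, 6336 differed, 4603 higher and 1733 lower at day 8. With median-of-ratios scaling the splits were 5286 to 6449 and 2469 to 2790, and with quantile normalization 7654 to 4619 and 2355 to 2796. The median of all genes was 0.72 for the former step and 0.20 for the latter. Of the short transcripts that fell by day 4, MIR6723 went from 27749.8 and 29460.3 TPM, MT-TA from 11832 and 12868 TPM and MT-TF from 2322 and 1716 TPM to listed at 0. MT-TL1 went from 5420.1 and 5613 TPM to 2.37 and 0 TPM, and MT-TS1 from 9537 and 8820.4 TPM to 5.30 and 3.03 TPM. MIR302A was at 18.5 and 27.2 TPM at day 4 and listed at 0 at day 8. SNORD117 was listed at 0 at day 4 and at 26.2 and 53.7 TPM at day 8. Its call was lost without any 1 of the 8 libraries of days 4 and 8 except WT1 and WT2 at day 8 (0.0539 to 0.149). The SOX21 change from day 4 to day 8, -0.19 (adjusted p = 0.836), was -1.11 without S13 at day 8 (adjusted p = 0.00695) and 0.73 without S23 (adjusted p = 0.0291). The count from day 4 to day 8 was 3884 without S13 at day 4 and 3634 without S23 at day 8.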

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

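The tests of abundant genes, of exchanged libraries, of reads from SOX21-AS1 and of the scaling at day 4 were chosen after the results were seen. The values listed first are differences of the genotype effect (libraries labelled SOX21-/- minus wild type) between days that passed the interaction test.

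Between days 0 and 4 the genotype effect differed for 99 genes. The largest upward differences were in SNORD87 (4.30), SNORA10 (4.30), SNORD1C (4.06), SNORD116-22 (4.00) and MIR6514 (3.67), and the largest downward ones in MIR663B (-7.68), SNORD116-14 (-4.77), SCNN1D (-3.90), SNORA5B (-3.66) and DDIT4 (-2.14), with adjusted p of 0.00122 to 0.0401. Between days 4 and 8 the effect differed for 270 genes, upward in MIR4701 (6.40), HES3 (4.24), FGFR2 (3.49), WLS (3.20) and MIAT (3.03) and downward in PKDCC (-4.99), DIO3 (-3.89), FZD5 (-3.65), ADCYAP1R1 (-3.58), MGST1 (-3.48), FZD8 (-2.88), SEMA5A (-2.37) and BEGAIN (-2.28), with adjusted p of 0.000967 to 0.0382. Between days 0 and 8 it differed for 228 genes, upward in WNT8B (7.27), HES3 (4.69), SNORA2A (4.66), SNORA5C (4.60) and WLS (4.38) and downward in MIR663B (-8.35), PKDCC (-4.83), SNORD116-14 (-4.77) and DLK1 (-4.26), with adjusted p of 0.000978 to 0.0175. For the small RNA genes at least 1 group was listed at 0, so those fitted differences depend on the pseudocount and are no fold changes. Between days 0 and 4 the values of SNORD87, SNORA10, SNORD1C, SNORD116-22, MIR6514, SNORD116-14 and SNORA5B equal their day 0 genotype effects with the sign reversed. These genes had no fitted genotype effect at day 4, so their differences only repeat the day 0 calls. The same holds for SNORD116-14 between days 0 and 8. Leaving out 1 library ended the day 0 to day 4 calls of SNORD87, SNORA10, SNORD116-22, MIR663B, SCNN1D and DDIT4 in 10 leave-outs each (adjusted p = 0.0501 to 0.131). It ended the day 4 to day 8 calls of BEGAIN in 11 (0.0578 to 0.127), MIAT in 10 (0.0534 to 0.127) and MIR4701 in 10 (0.0510 to 0.101), of FZD8 without WT1 at day 4 or WT2 or S23 at day 8 (0.05003 to 0.0590) and of SEMA5A without WT1 at day 4 or WT2 at day 8 (0.0503 to 0.0510), and the day 0 to day 8 calls of DLK1 and MIR663B in 6 each (0.0525 to 0.0709 and 0.0561 to 0.0693).

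Most tested genes differed between days 0 and 4 in both genotypes. Of the 15931 wild-type calls, 8311 were also made in the same direction under median-of-ratios scaling, which argues against a few abundant genes at day 0 as the source of all calls and leaves this open for the 6088 calls that ended and the 1532 that turned. Neural differentiation, the biological explanation, predicted a higher median change for the early neural list than for the pluripotency list. The difference was 4.77 in the libraries labelled SOX21-/- and 4.81 in wild type. These markers bear on whether the cells differentiated and cannot show why most tested genes differed. Day 0 libraries may also have been prepared or read in another way. The change correlated with transcript length at a Spearman rho of 0.196 in the libraries labelled SOX21-/- and 0.205 in wild type. From day 4 to day 8 rho was 0.0286 and 0.00724, and a bound of 0.2 was set in advance. The makeup of gene types also set day 0 apart. Processed pseudogenes held 11.1% to 12.4% of the TPM at day 0 and 0.454% to 0.677% at days 4 and 8. For mitochondrial tRNA genes the shares were 6.57% to 8.40% and 0.0588% to 0.0713%. These explanations cannot be told apart for single genes, since all 4 day 0 libraries share their day and the sequencer of each library is not given.

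SOX21 mRNA was not called lower in the libraries labelled SOX21-/- than in wild type. An exchange of 1 labelled library with a wild-type one at day 4 or 8 is argued against by WNT8B, whose lower value in S13 and S23 was 8.38 times the higher wild-type value at day 4 and 189.7 times at day 8. Reads of SOX21-AS1 counted for SOX21 are unlikely to be the source, since the exons of the genes share 0 bases and lie 316 bases apart. A mutation that leaves the mRNA in place, such as a small deletion in the coding sequence, stays open and was not tested, since gene-level TPM does not show it. A wrong genotype for all labelled libraries also stays open.

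More genes were lower than higher at day 4 in the libraries labelled SOX21-/-. The scaling of the TPM cannot be told apart from a true excess of lower genes: the share of higher genes was 30.9% as deposited and at least 56.2% under 2 scalings, but both centre the change of all genes at 0, which by itself shifts the split. Depth also stays open and was not tested, with fewer genes at 1 TPM in both labelled libraries at day 4. A lag of the labelled cells in differentiation was not decided, since the genotype effect at day 4 correlated with the later wild-type change at 0.00279 and -0.00798 when each used another wild-type day 4 library, against 0.286 when they shared both. The lag cannot be told apart from no lag, because by the bounds set in advance both values had to lie under -0.1 for a lag or over 0 for none, and only the first was over 0.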

How the results depend on the processing

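Fits on nuclear protein-coding genes only, on days 4 and 8 only and on both together were chosen after the data were seen, and the other alternatives before. Called values of named genes numbered 213 and were compared in 4759 pairs of a value and an alternative, which share the same few fits. Of these pairs 3670 kept the call, 1089 lost it and 0 changed direction. For the largest changes between genotypes the naming rule fixed the direction in advance when 1 library was left out. The 42 uncalled values gave 902 pairs, in which 21 became called and 1 changed direction with a call. The 18 called lists gave 349 pairs, of which 283 kept the call, 65 lost it and 1 changed direction, taken from the list test. In 3 of the lost calls the median also changed sign, for hypoxia without WT1 at day 0 (-0.032), the mitochondrially encoded list without S13 at day 4 (-0.035) and cell cycle without S23 at day 8 (0.0075). The 2 that changed direction were the mitochondrially encoded list at day 4, with a median of -0.0834 under quantile normalization (adjusted p = 0.142), and SOX21 from day 4 to day 8 in the libraries labelled SOX21-/-, at 0.73 without S23 at day 8 (-0.19 as fitted, -1.11 without S13). Counts that moved over 1.5 times follow, and the cause was not tested except where fewer libraries or genes entered the fit. At day 0 the count of 93 became 159 without a filter, 154 with median-of-ratios scaling, 8 with protein-coding genes only and 45 with day 0 alone. At day 4 the count of 188 became 97 with median-of-ratios scaling, 107 with robust variances, 123 at 2-fold, 406 with protein-coding genes of days 4 and 8, and 0 by limma with days 4 and 8 or day 4 alone (3874 and 3288 at an unadjusted p under 0.05). At day 8 the count of 676 became 312 with days 4 and 8 and 34 with day 8 alone. The wild-type step from day 0 to day 4 went from 15931 to 10499 with protein-coding genes only. The interaction counts became 154 with a pseudocount of 0.1, 104 with median-of-ratios scaling and 45 with days 4 and 8 (days 4 and 8; 270 as fitted). They became 58 at a TPM of 5, 163 without a filter and 26 with protein-coding genes only (days 0 and 4; 99 as fitted), and 147 at a TPM of 5 (days 0 and 8; 228 as fitted). Of 90 list tests, 18 were called by camera, 0 with an estimated correlation (lowest adjusted p = 0.264), 8 by directional fry and 59 by mixed fry. Leaving out 1 library, where the lone library of a group was assumed to vary like those of the other groups, gave 59 to 114 genes at day 0, 14 to 191 at day 4, 170 to 774 at day 8, 14255 to 16005 and 1038 to 3188 for the wild-type steps. It gave 12935 to 14688 and 3634 to 6162 for the other steps, 38 to 80, 54 to 242 and 89 to 209 for the interactions (days 0 and 4, 4 and 8, 0 and 8), and 12 to 23 lists. Unknown depth limits what can be said of genes with low values.

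Replicate numbers were also tried as a replicate block. Differences between the libraries of a genotype correlated between days at -0.00603 to 0.0712. The highest was between days 4 and 8 in the libraries labelled SOX21-/-. Such correlations across all genes cannot decide whether a repeated number marks the same clone or culture. With the replicate block the day steps called 15721 and 2142 genes in wild type and 14420 and 5536 in the libraries labelled SOX21-/-, and the interactions 22 (days 0 and 4), 17 (days 4 and 8) and 98 (days 0 and 8). It ended 9 of the day 0 to day 4 calls of genes followed (adjusted p = 0.0590 to 0.105), 7 of those from day 4 to day 8 (0.0517 to 0.112) and 1 from day 0 to day 8 (0.0634). With the line label as a random effect 93, 188 and 672 genes were called between genotypes at days 0, 4 and 8.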

Other observations

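A group of genes in and beside an imprinted region, chosen after its values were seen, was lower at day 8 in the libraries labelled SOX21-/-. BEGAIN (chromosome 14, 100537147 to 100587413), DLK1 (chromosome 14, 100725705 to 100738224) and DIO3 (chromosome 14, 101561351 to 101563452) lie in 1 region of GRCh38, which also holds RTL1 and the noncoding gene MEG3. In wild type DLK1 went from 529 and 608 TPM at day 4 to 3194 and 2908 TPM at day 8, and in S13 and S23 from 261 and 319 TPM to 339 and 114 TPM. At day 8 BEGAIN was at 9.23 and 5.34 TPM in S13 and S23 and 103 and 91.5 TPM in wild type, DIO3 at 0.889 and 0.284 TPM and 19.3 and 21.7 TPM, RTL1 at 0.385 and 0.0728 TPM and 2.64 and 2.90 TPM, and MEG3 at 3.44 and 0.819 TPM and 20.5 and 17.8 TPM. The limma log2 fold changes were -3.60, -3.95, -3.79, -1.63 and -2.82 for BEGAIN, DLK1, DIO3, RTL1 and MEG3 (adjusted p = 0.000492, 0.00281, 0.000410, 0.00642 and 0.00743), and MEG3 was not called without WT1 or WT2 at day 8 (adjusted p = 0.0511 and 0.0559). No test of the region as a whole was made.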
